A study of Rattus norvegicus with 6 samples.

How the data were processed

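CD45-sorted lung cells of Sprague Dawley rat pups in 6 samples, 3 in the control group (NS-RA) and 3 in the exposed group (LPS-O2), were sorted straight into RLT lysis buffer, homogenised and frozen, per the labels' protocols. Total RNA was isolated with a Qiagen AllPrep kit, and biotin-labelled cDNA was prepared with the WT-Plus kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, whose CD45 tag and the label of pulmonary immune cells give the gate. The design text calls the samples biological replicates and does not say whether a sample came from 1 pup or a pool. The labels do not give the sex of the pups.

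The values are log2 values as deposited by the authors in 1 table of 23188 probe sets for the 6 arrays, rounded to 2 decimals. Transcriptome Analysis Console is named for the processing, without a version, per the submitters' processing notes. The array type, the background correction, the normalization and the base of the logarithm are not given in the sources used here. The log2 scale was inferred from the range of the deposited values, 2.01 to 19.93, and from array medians that agree within 0.06 between the lowest (5.39) and the highest (5.45). No detection calls came with the values, so no probe set could be called absent. Differences of genes near the bottom of the range are uncertain in size, and so are those near the top, where the signal may saturate. No further normalization was applied for the main results.

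Gene names came from the platform's annotation table of the probe sets, as written there. The RefSeq gene table of assembly GRCr8 served only to match entries of the gene lists through synonyms. Of the probe sets, 15049 had 1 gene symbol, 0 had several and 8139 had none here, which does not mean that they have no gene. The named probe sets covered 15037 genes. For a gene with several probe sets, the one with the highest mean over the 6 arrays was used, and none of the genes named in the text has more than 1. Since the array's genome build is not named, no coordinates are given. Genes with near-identical copies, such as Hspa1a, Hba-a1, the mast cell proteases, the Fc receptors, the RT1 class II genes and the Gimap family, can share probe signal with those copies.

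The comparison of LPS-O2 with NS-RA was fitted with limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes on the log2 values of all 6 arrays, two-sided, and with Benjamini-Hochberg adjustment over the 23188 probe sets. A probe set was called at an adjusted p under 0.05. Adjusted p-values of single genes in the text are from this fit unless another is named. Errors of means are SD over 3 arrays, and errors of log2 differences of genes are the fit's SE. Errors of list shifts are the SE of an ordinary linear model of the list's mean per array on the group, over the 6 arrays. The word rose or fell is used for called genes. Figures were drawn with matplotlib 3.10.9.

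Before the data were examined, 43 gene lists were written from general knowledge, 17 of cell types that the CD45 gate should hold or remove and 26 of pathways that infection and high oxygen could move, with 3 more lists (leukocyte gate, Y-linked genes, X inactivation) used as checks. Of 1219 entries, 1050 were measured, 14 of them matched through a RefSeq synonym. The X inactivation list had no measured gene. Lists were tested with limma's camera at a preset correlation of 0.01 on 1 probe set per gene, with Benjamini-Hochberg adjustment over the 43 lists, and again with the correlation estimated from the residuals and with fry. Genes called after adjustment within a list are counted as adjusted over the list alone.

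The genes named in the text followed a rule fixed at the same time. It took the 12 called genes with the largest rise and the 12 with the largest fall whose group values did not overlap. From each list it took up to 2 called members with the largest rise and 2 with the largest fall, or, if none was called, the 2 with the smallest p. It added fixed genes, among them Ptprc, Ccr2, Il1b, Tnf, Il6, Il10, Nos2, Arg1, Hmox1, Tlr4, Cd14, Sftpc and Col1a1. The rule left out symbols of predicted genes and of red cells from the largest changes. It named 122 genes, of which 2 are not reported here. Genes outside the rule are said to have been named after their values were seen.

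The fit was tested on simulated data with the probe set means of these arrays. The spread was drawn at random from the distribution that limma had fitted, with independent normal noise. These are the fit's own assumptions, so the shares of false calls do not cover an outlying array or correlated genes. With 200 of the 23188 probe sets changed, 0% of 1.5-fold, 8% of 2-fold, 90% of 4-fold and 98% of 8-fold changes were called, and 6.67% of the calls were false. With 10% of the probe sets changed, 11.2% of 1.5-fold, 57.4% of 2-fold, 98.1% of 4-fold and 99.8% of 8-fold changes were called, and 4.98% of the calls were false. In simulated lists of independent genes, a T cell list shifted by -1 was recovered by camera, by camera with an estimated correlation (adjusted p = 0.00705) and by fry (adjusted p = 0.00197), with 0 false list calls. Genes of the real lists are correlated (estimated at 0.335 for the T cell list). The simulation therefore does not show how many false list calls camera makes at the preset correlation.

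Alternatives fixed together with the lists were leaving out each array in turn, the replicate number as a block, leaving out the dimmest 33.3% of probe sets, quantile normalization, median centring, eBayes with trend and robust, array weights, other thresholds, 1 probe set per gene, the mean of a gene's probe sets, an estimated correlation, fry, and lists without shared genes. Added after seeing the data were the mean of Ddx3y and Eif2s3y as a covariate (the Y-linked covariate), control replicate 3 alone against the LPS-O2 arrays, and Hba-a1 as a covariate. The differences between list shifts were also fitted with these covariates, with each array left out and without shared genes. Such a difference was read as evidence only if the median of the comparison list lay below the other shift by more than the SD over its genes, with and without shared genes, a condition added after the differences were seen. An alternative for linear values (the pseudocount before taking logarithms) was not needed.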

Results

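Gene expression was measured with microarrays in immune cells sorted from the lungs of 2-week-old Sprague Dawley rat pups through CD45, the leukocyte common antigen. The control group (NS-RA, 3 arrays) had received saline into the amniotic sac before birth and breathed normal air after it. The exposed group (LPS-O2, 3 arrays) had received lipopolysaccharide, a bacterial wall component used to model chorioamnionitis, into the amniotic sac and was kept in high oxygen after birth. The combined exposure is a rat model of bronchopulmonary dysplasia, the chronic lung disease of infants born preterm, and the comparison asks how the transcriptome of lung leukocytes differs after it. Both exposures were given to the same group, so their separate shares cannot be told apart. The design text calls the 3 samples of each group biological replicates. The deposited table held log2 values of 23188 probe sets per array, with array medians from 5.39 to 5.45. The number of arrays limits the precision of every value given here.

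The arrays separated by group on the first principal component, which held 44.8% of the variance, with controls from -50.9 to -37.3 and LPS-O2 from 39.4 to 46.3. LPS-O2 replicate 1 stood apart on the second component (18.8% of the variance) at -48.9, against -22.5 to 30.7 for the other arrays. Across probe sets, which are not independent replicates, correlations were 0.983 to 0.990 within groups and 0.973 to 0.981 between them. Ptprc, which encodes CD45, was among the brightest genes at 17.53 ± 0.02 in controls and 16.69 ± 0.30 in LPS-O2 (log2, SD, n = 3 per group). Its difference of -0.84 did not pass (limma adjusted p = 0.0686), but did without LPS-O2 replicate 1 (adjusted p = 0.0397), with array weights (0.0392) and with trend and robust in eBayes (0.0182). The brightness of Ptprc does not show how pure the sort was. Sftpc, a gene of alveolar type II cells that the gate should remove, was brighter at 18.06 ± 0.72 in controls and 17.95 ± 0.86 in LPS-O2 (SD). Of the 14 measured genes of the leukocyte gate list, 3 fell, and 4 when adjusted over the list alone. These 3 were Cytip (-1.90 ± 0.28, SE), Ptprcap (-1.50 ± 0.31) and Itgb2 (-1.08 ± 0.24). The calls of Ptprcap and Itgb2 were each lost in 5 of the 6 fits that left out 1 array, with adjusted p up to 0.119 and 0.154, both without LPS-O2 replicate 2.

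Samples also differed in ways the group labels do not state, and Y-linked genes were low in 2 of the 3 controls alone, so if they follow the sex of the pups, sex is partly confounded with the exposure in the 880 calls too (501 with the Y-linked covariate). The Y-linked gene Ddx3y was 3.51, 6.34 and 11.57 in control replicates 1, 2 and 3, and 11.55, 11.14 and 11.05 in LPS-O2 replicates 1, 2 and 3, and the Y-linked Eif2s3y ran alongside (5.43, 7.41 and 12.44 in controls, 12.28 to 12.77 in LPS-O2). Neither gene passed (Ddx3y adjusted p = 0.218; Eif2s3y adjusted p = 0.164), but without control replicate 3 both did (adjusted p = 0.00715 and 0.00234), and with Hba-a1 as a covariate (0.0161 and 0.0160). Haemoglobin Hba-a1, a red cell transcript, was 10.19, 13.47 and 15.48 in the controls and 13.22, 10.3 and 10.37 in LPS-O2. The mean of the neutrophil list was 11.4 in LPS-O2 replicate 1, 9.87 and 9.10 in the other LPS-O2 arrays, and 9.33 to 10.1 in controls. Xist, transcribed from the inactive X chromosome, had no probe set named here.

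**Figure D1:**
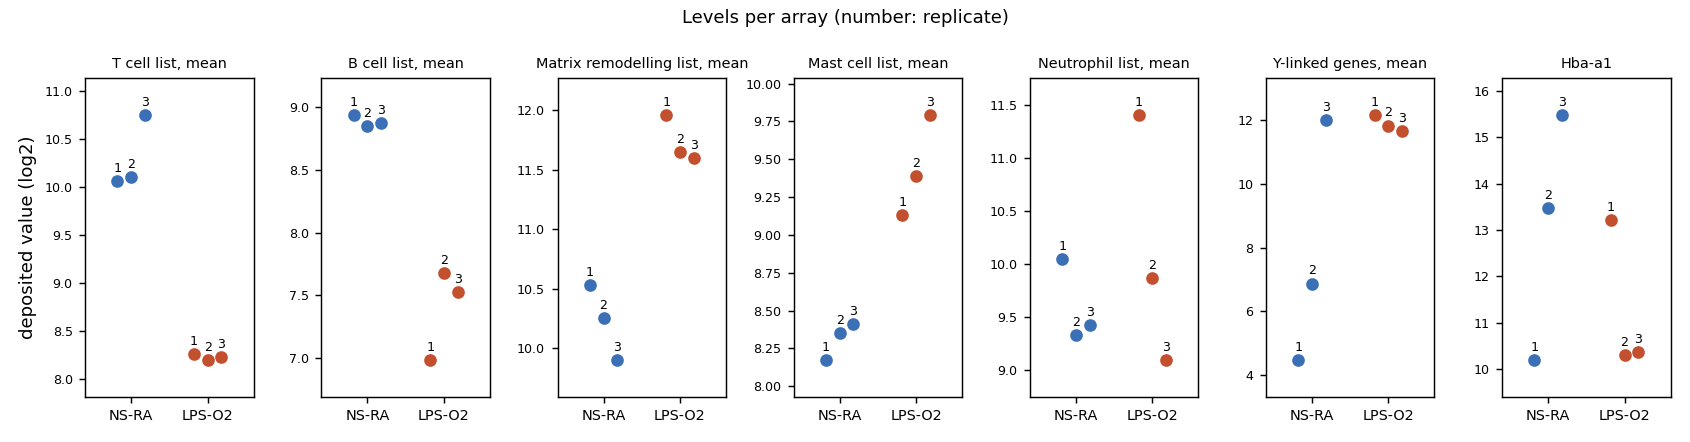
Levels per array in log2 units (vertical axes, which differ between panels) for the mean of 5 gene lists, the mean of the Y-linked genes Ddx3y and Eif2s3y, and Hba-a1, with blue points for NS-RA and red points for LPS-O2 and the replicate number beside each point. T cell list means were 10.1 to 10.8 in controls and 8.20 to 8.26 in LPS-O2, while the Y-linked mean was 4.47 and 6.88 in control replicates 1 and 2 and at least 11.7 in the other 4 arrays.

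Expression changed broadly between the groups. At a limma adjusted p under 0.05, 880 of 23188 probe sets (3.80%) were called, 382 higher and 498 lower in LPS-O2, and 790 of them differed by at least 2-fold. The calls covered 640 named genes, 301 higher and 339 lower, and 240 probe sets without a gene name here. In all 880 the values of the groups did not overlap, as held for 21.9% of all probe sets, against 10% by chance. The number of calls depended on single arrays. It was 275 without control replicate 2, 312 without LPS-O2 replicate 2, 384 without LPS-O2 replicate 3, 512 without control replicate 3, 554 without control replicate 1 and 899 without LPS-O2 replicate 1. With the Y-linked mean as a covariate, chosen after seeing the data, 501 probe sets were called, of which 370 were among the 880. Setting control replicate 3 alone against the 3 LPS-O2 arrays, also chosen after seeing the data and with the lone control assumed to vary like the LPS-O2 arrays, left 182 calls, of which 162 were among the 880.

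The largest rise was that of Spp1, which encodes osteopontin, a secreted matrix phosphoprotein. It was 4.63 ± 0.59 in controls, below the array medians, and 13.05 ± 1.09 in LPS-O2 (SD, n = 3 per group), a log2 difference of 8.42 ± 0.50 (SE; limma adjusted p = 0.000317). With the control values at the dim end of the scale, the fold of 342 is uncertain. The chemokines Ccl17 (5.18 ± 0.57), Ccl7 (4.67 ± 0.68) and Ccl22 (4.57 ± 0.61) rose, as did Emp1 (5.13 ± 0.40), an epithelial membrane protein gene. Timp1, an inhibitor of matrix metalloproteinases, rose by 4.49 ± 0.51 and the metalloproteinases Mmp14 and Mmp12 by 4.24 ± 0.59 and 3.94 ± 0.45. Fabp5, a fatty acid binding protein gene, rose by 4.16 ± 0.26 and the inhibitory Fc receptor gene Fcgr2b by 3.99 ± 0.53. Pld3 (4.16 ± 0.68; adjusted p = 0.0761 with trend and robust in eBayes) and Enpp3 (3.90 ± 0.60), a surface enzyme of basophils and mast cells, completed the 12 largest rises. Pld3 missed the threshold without LPS-O2 replicate 2 or 3 (adjusted p = 0.0592 and 0.0585), and Enpp3 without control replicate 2 (0.0507) and with the Y-linked covariate (0.0700).

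The largest fall was that of Serpinb10, a serine protease inhibitor gene, from 13.60 ± 1.0 to 8.56 ± 0.80 (SD), a difference of -5.04 ± 0.52 (SE; limma adjusted p = 0.00193). The gap junction gene Gjb2 fell by 4.10 ± 0.21, from 10.81 ± 0.12 to 6.72 ± 0.27. The sphingosine-1-phosphate receptor gene S1pr5 fell by 3.80 ± 0.26. Qrfpr (-3.60 ± 0.35), the T cell receptor complex gene Cd3e (-3.47 ± 0.26) and Mal (-3.46 ± 0.34), a T cell membrane proteolipid gene, fell as well. Falls of similar size in Pla2g2d (-4.07 ± 0.64; adjusted p = 0.0620 with trend and robust in eBayes), a secreted phospholipase, and Cidec (-3.84 ± 0.65), a lipid droplet protein, were lost without control replicate 2 (adjusted p = 0.0550) and LPS-O2 replicate 2 (0.0703), in that order, and with the Y-linked covariate (0.0792 and 0.114). The remaining 4 of the 12 largest falls were called in 1 to 3 of the 6 fits that left out 1 array. They were Hspa1a (-3.82 ± 0.88), Sirpb3 (-3.79 ± 0.78), the zinc transporter gene Slc39a2 (-3.48 ± 0.76) and Gpd1 (-3.48 ± 0.70), whose adjusted p reached 0.160, 0.118, 0.118 and 0.105 without control replicate 2 and 0.167, 0.198, 0.255 and 0.146 with the Y-linked covariate. Of the 12 largest falls, 7 stayed past the threshold without control replicate 2 and 7 without LPS-O2 replicate 2. Hspa1a has a near-identical copy, and the signal may be shared.

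**Figure D2:**
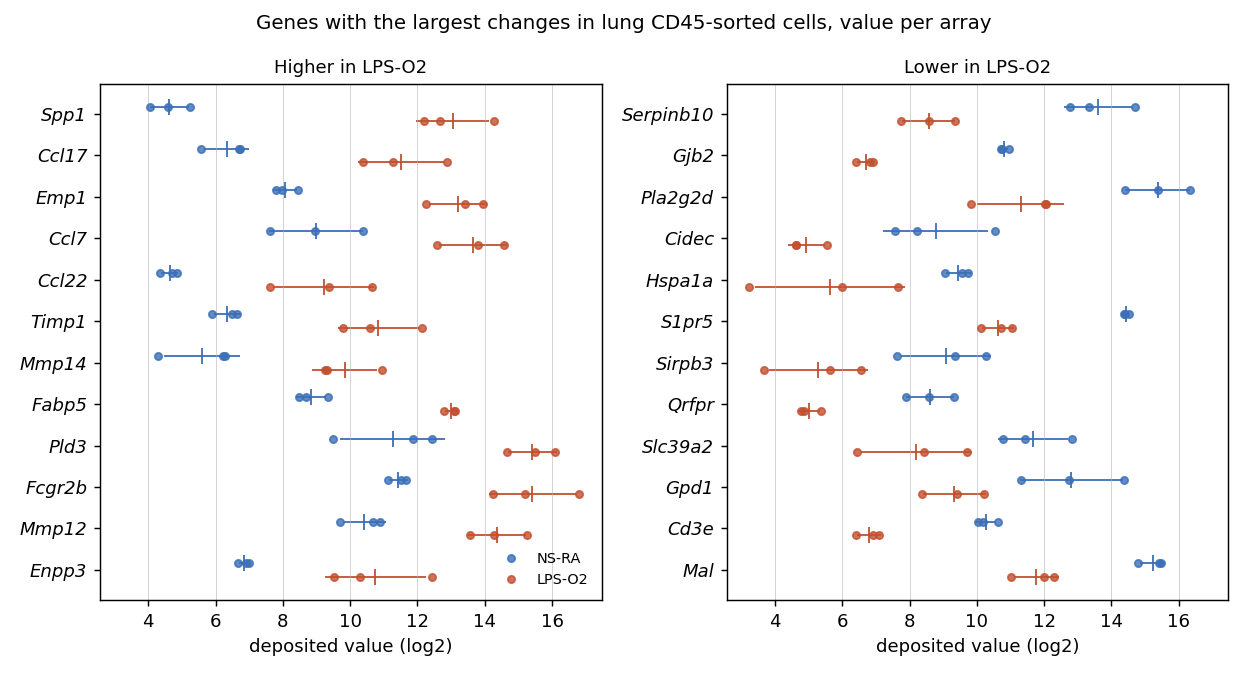
Deposited log2 values (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per array, blue for NS-RA and red for LPS-O2, a vertical tick at the group mean and a horizontal bar of 1 SD (n = 3). The 3 points of one group lie apart from the 3 of the other for each gene, with Spp1 from 4.06 to 5.23 in controls and 12.2 to 14.3 in LPS-O2.

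Lymphocyte genes were lower in LPS-O2. Of 21 measured T cell genes, 18 fell and none rose, and 20 fell when adjusted over the list alone. The list mean fell by 2.08 ± 0.22 (SE), and camera gave an adjusted p = 1.99e-26 (adjusted p = 0.105 with an estimated correlation). Besides Cd3e, the largest fall was in Lef1 (-3.37 ± 0.32), a transcription factor of naive T cells. Ccr7, the chemokine receptor that guides naive T cells and mature dendritic cells to lymph nodes, fell by 2.28 ± 0.19, from 14.41 ± 0.11 to 12.13 ± 0.04 (SD, n = 3). Of the 18 genes, 12 stayed past the threshold whichever array was left out, 15 with the Y-linked covariate and 15 with Hba-a1 as a covariate. Of 15 B cell genes, 8 fell (12 lower and 2 higher when adjusted over the list alone; list mean -1.49 ± 0.21; camera adjusted p = 9.52e-11, adjusted p = 0.105 with an estimated correlation). Cd79b, a chain of the B cell receptor, fell by 3.31 ± 0.52 and the B lineage factor Ebf1 changed by -2.92 ± 0.33. Without control replicate 2, 5 of the 8 stayed past the threshold, and Cd79b did not (adjusted p = 0.0597). Setting control replicate 3 alone against the LPS-O2 arrays, 13 of the T cell genes and 1 of the B cell genes passed. The 8 plasma cell genes gave no call (camera adjusted p = 0.867), also when adjusted over the list alone, and the 2 with the smallest p were Txndc5 (0.83 ± 0.27, adjusted p = 0.151) and Sdc1 (1.84 ± 0.63, adjusted p = 0.166). Hba-a1, a sign of blood, averaged higher in these controls than in LPS-O2, with overlapping values.

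The cytotoxic and regulatory lists were called as lower. Of 20 natural killer and cytotoxic cell genes, 3 fell and 1 rose (6 and 1 when adjusted over the list alone), with a list mean of -0.68 ± 0.30 (camera adjusted p = 0.000174; adjusted p = 0.409 with an estimated correlation). The mean was -0.437 without control replicate 3, -0.442 with Hba-a1 as a covariate, -1.19 with the Y-linked covariate and -1.15 with control replicate 3 as the only control. Granzyme A (Gzma) fell by 2.83 ± 0.41, perforin (Prf1) changed by -2.59 ± 0.51, Ccl5 fell by 1.64 ± 0.35, and the chemokine gene Xcl1 rose by 1.45 ± 0.20. Gzma and Xcl1 kept their calls whichever array was left out. Prf1 and Ccl5 lost theirs in every such fit except that without control replicate 1 (adjusted p up to 0.113 for Prf1 and 0.128 for Ccl5, both without control replicate 2), and Prf1 also with trend and robust in eBayes (0.0636). Of 13 regulatory T cell and checkpoint genes, 2 fell (4 when adjusted over the list alone; list mean -0.55 ± 0.20; camera adjusted p = 0.0166, adjusted p = 0.292 with an estimated correlation). These were Foxp3 (-2.24 ± 0.36), the lineage factor of regulatory T cells, and Tnfrsf18 (-1.57 ± 0.32). Foxp3 missed the threshold without LPS-O2 replicate 2 (adjusted p = 0.0570) and with the Y-linked covariate (0.0711), and Tnfrsf18 in every fit with 1 array left out except that without control replicate 2 (up to 0.0928). The list call itself was lost without control replicate 1 (mean -0.364, adjusted p = 0.118), with the Y-linked covariate (mean -0.349, adjusted p = 0.200) and with control replicate 3 as the only control (0.109). Of 22 lymphocyte effector cytokine genes, 1 passed over all genes and 1 over the list alone. It was Gata3 (-1.66 ± 0.38), which directs type 2 responses and lost its call in each of the 6 fits with 1 array left out (adjusted p from 0.0582 to 0.144); the list was not called (camera adjusted p = 0.863).

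The list of interstitial and monocyte-derived macrophages was called as higher. Of 20 genes of interstitial and monocyte-derived macrophages, 5 rose and none fell (15 higher when adjusted over the list alone), and the list mean rose by 1.63 ± 0.54 (camera adjusted p = 1.51e-09; adjusted p = 0.335 with an estimated correlation; mean 1.08 without shared genes). Apolipoprotein E (Apoe) rose by 3.59 ± 0.67 to 17.09 ± 0.72 (SD, n = 3; not passing with trend and robust in eBayes, adjusted p = 0.126) and the monocyte chemoattractant gene Ccl12 by 3.09 ± 0.47 (not passing without control replicate 2, adjusted p = 0.0547). The other called genes, named after their values were seen, were Folr2 (3.08 ± 0.54), Pf4 (3.05 ± 0.49) and the scavenger receptor gene Cd163 (3.03 ± 0.56). All 5 kept their calls with the Y-linked covariate, but 3 did without control replicate 2, 1 without LPS-O2 replicate 2 and 2 without LPS-O2 replicate 3. The complement gene C1qa, fixed for naming beforehand, was 1.96 ± 0.50 higher without passing (adjusted p = 0.0697), and passed without LPS-O2 replicate 1 (0.00721) and with array weights (0.0354). Of 21 alveolar macrophage genes, 2 fell (2 lower and 2 higher when adjusted over the list alone), both named above, Cidec and Slc39a2. That list was not called (camera adjusted p = 0.641; median 0.09 and mean -0.36) but was as lower with Hba-a1 as a covariate (mean -0.691, adjusted p = 0.0484), while its mean was -0.0144 without control replicate 1, -0.685 without control replicate 3, 0.341 with the Y-linked covariate and 0.297 with control replicate 3 as the only control, and the scavenger receptor gene Marco stayed below the array medians in both groups (adjusted p = 0.476). Cidec and Slc39a2 both missed the threshold without LPS-O2 replicate 2. The difference between the shifts of these macrophage lists was 1.99, with a 95% interval of 0.856 to 3.12 (-0.0319 to 4.03 with the Y-linked covariate). Of the interstitial list 10 genes and of the alveolar list 14 are also in other lists.

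Of 20 monocyte genes, 7 fell and none rose (8 lower and 4 higher when adjusted over the list alone). The low-affinity Fc receptor gene Fcgr3a fell by 3.16 ± 0.63 and Hes1, a Notch target, changed by -2.35 ± 0.28. The list mean fell by 0.33 ± 0.28 (camera adjusted p = 0.0191; adjusted p = 0.431 with an estimated correlation), and the list call was lost without LPS-O2 replicate 3 (mean -0.176, adjusted p = 0.0901), with the replicate block (0.0570) and with Hba-a1 as a covariate (mean -0.160, 0.0995). Its mean in LPS-O2 replicate 1 (14.34) lay above those of the controls (14.04 to 14.17), and the shift was -0.603 without that array and -0.215 without LPS-O2 replicate 2. Of the 7 genes, 4 stayed past the threshold without control replicate 2 and 4 without LPS-O2 replicate 2, where Fcgr3a had an adjusted p = 0.114 and 0.109 (0.0900 with trend and robust in eBayes). The chemokine receptor gene Ccr2 of classical monocytes was 18.26 ± 0.50 in controls and 18.70 ± 0.41 in LPS-O2 (SD, n = 3; adjusted p = 0.540). Of 20 neutrophil genes none passed, also when adjusted over the list alone (camera adjusted p = 0.134), with S100a8 at 14.18 ± 0.25 and 14.75 ± 2.17 and S100a9 at 16.43 ± 0.38 and 16.74 ± 1.71. Elane (0.88 ± 0.26, adjusted p = 0.110) and Lcn2 (2.93 ± 0.97, adjusted p = 0.153) had the smallest p of that list. Without LPS-O2 replicate 3 Lcn2 passed (adjusted p = 0.0452), and the neutrophil list was called as higher without control replicate 1 (0.0342), LPS-O2 replicate 2 (0.0412) or LPS-O2 replicate 3 (0.000314), with the replicate block (0.0286) and with Hba-a1 as a covariate (0.0398). Each of these fits kept LPS-O2 replicate 1, the only LPS-O2 array whose list mean (11.4) lay above the controls (9.33 to 10.1). LPS-O2 replicates 2 and 3 were at 9.87 and 9.10.

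Mast cell and dendritic cell genes were higher. Of 18 mast cell and basophil genes, 8 rose and none fell, and 8 rose when adjusted over the list alone (list mean 1.13 ± 0.20; camera adjusted p = 5.27e-07, adjusted p = 0.263 with an estimated correlation). Cma1, which encodes a mast cell chymase, rose by 3.48 ± 0.31, from 6.99 ± 0.53 to 10.47 ± 0.41 (SD, n = 3), and Enpp3 was among the largest rises above. Also called, and named after their values were seen, were the protease genes Mcpt1 (2.90 ± 0.26), Cpa3 (2.45 ± 0.25) and Tpsab1 (1.83 ± 0.33), the receptor gene Kit (1.30 ± 0.30), the transcription factor gene Gata2 (1.25 ± 0.24) and the basophil protease gene Mcpt8 (1.07 ± 0.21). Of the 8, 3 stayed past the threshold whichever array was left out, 4 without control replicate 2, control replicate 3 or LPS-O2 replicate 3, 5 without control replicate 1 or LPS-O2 replicate 2, and 3 with the Y-linked covariate. Mast cell proteases are a family of similar genes, so signal may be shared among them. Of 19 dendritic cell genes, 6 rose and none fell (9 higher and 2 lower when adjusted over the list alone; list mean 1.15 ± 0.16; camera adjusted p = 1.25e-05, adjusted p = 0.149 with an estimated correlation). Besides Ccl17 and Ccl22 they included Xcr1 (1.93 ± 0.24), the receptor of cross-presenting dendritic cells, and Tlr3 (1.65 ± 0.27), which missed the threshold without control replicate 2 (adjusted p = 0.0602) and with the Y-linked covariate (0.0659). Without the genes that other lists share, the dendritic cell list had a mean of 0.397 and was not called (adjusted p = 0.219). Of 10 eosinophil genes, 1 fell (2 when adjusted over the list alone), the lipoxygenase gene Alox15 (-3.05 ± 0.36). The eosinophil list was called as lower (camera adjusted p = 0.0275; adjusted p = 0.263 with an estimated correlation), but not without control replicate 2 (0.0852), LPS-O2 replicate 1 (0.129) or LPS-O2 replicate 3 (0.101), without the dim probe sets (0.147) or without shared genes (mean -0.265, 0.126).

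**Figure D3:**
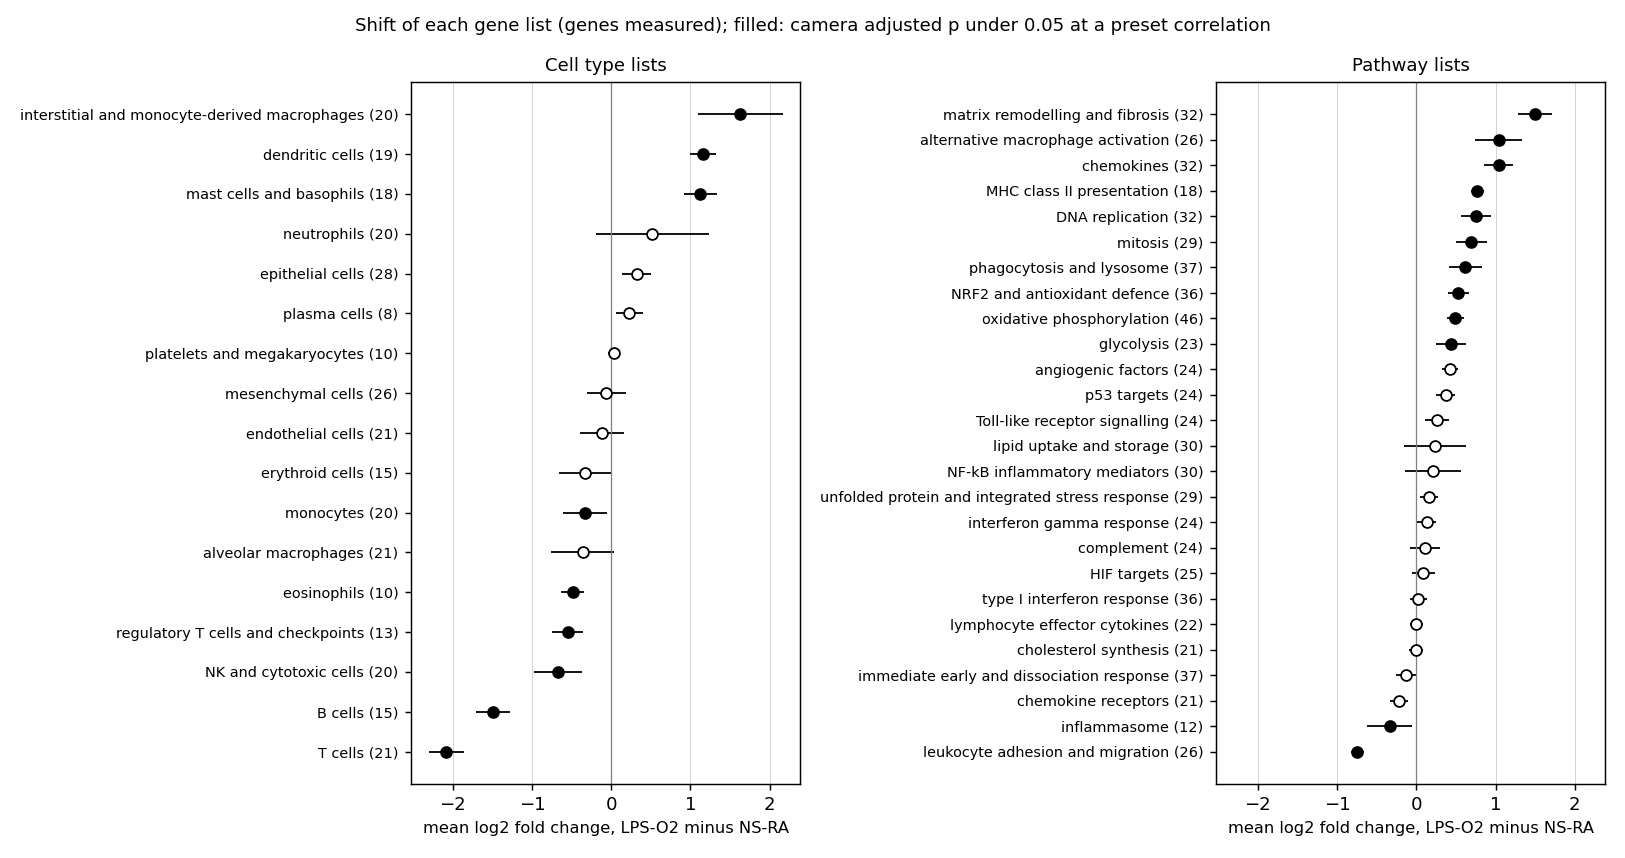
Mean log2 fold change of LPS-O2 minus NS-RA (horizontal axis) of the 17 cell type lists and 26 pathway lists, with the number of genes measured in parentheses, bars of 1 SE of the difference between the groups' list means (n = 3 per group) and filled points where camera with a preset correlation of 0.01 called the list. The T cell list lies lowest at -2.08 and the interstitial macrophage list highest at 1.63, and no list was called with an estimated correlation.

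No list of a cell type that the CD45 gate should remove was called over all 6 arrays, but some were under other settings. Of 28 epithelial genes, 4 rose (5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.164, but called as higher without control replicate 1, 0.0334, or LPS-O2 replicate 2, 0.0352, and with the Y-linked covariate, 0.0436), with podoplanin (Pdpn) higher by 2.83 ± 0.39 and E-cadherin (Cdh1) by 2.13 ± 0.38. None of the 4 kept its call with the Y-linked covariate, and Cdh1 lost it without control replicate 2 (adjusted p = 0.0812), control replicate 3 (0.0501) or LPS-O2 replicate 3 (0.0674). Of the 4 genes, 1 passed without control replicate 2, 1 without control replicate 3, 2 without control replicate 1 and 2 without LPS-O2 replicate 2. Surfactant protein C (Sftpc), made by alveolar type II cells, was bright in both groups at 18.06 ± 0.72 and 17.95 ± 0.86 (SD, n = 3; adjusted p = 0.951). Of 21 endothelial genes, 2 rose and 1 fell (3 and 4 when adjusted over the list alone; camera adjusted p = 0.277, but called as lower without control replicate 1, 0.0342, or LPS-O2 replicate 3, 0.0205, with the Y-linked covariate, 0.0302, and with control replicate 3 as the only control, 0.0353). Endoglin (Eng), a TGF-beta coreceptor, rose by 3.01 ± 0.27 and Esam by 1.65 ± 0.28, while Pecam1, an adhesion molecule that leukocytes also carry, fell by 2.39 ± 0.32. Esam missed the threshold without control replicate 2 (adjusted p = 0.0588), LPS-O2 replicate 2 (0.0664) or LPS-O2 replicate 3 (0.0530). None of 26 mesenchymal genes passed, over all genes or the list alone (camera adjusted p = 0.469, and called as lower without LPS-O2 replicate 3, 0.0459). The 2 with the smallest p were elastin (Eln, -0.91 ± 0.35, adjusted p = 0.220) and biglycan (Bgn, 0.80 ± 0.37, adjusted p = 0.320), and collagen Col1a1 was 8.47 ± 0.75 and 8.10 ± 0.42 (SD; adjusted p = 0.707). None of 15 erythroid genes passed either, over all genes or the list alone (camera adjusted p = 0.494; called as lower with the Y-linked covariate, 0.0203, and with control replicate 3 as the only control, 0.0358), with Fech at 0.78 ± 0.25 (adjusted p = 0.137) and Hbb at -2.07 ± 0.91 (adjusted p = 0.290; 0.0497 with the Y-linked covariate). Of 10 platelet and megakaryocyte genes, 1 fell, over all genes and over the list alone (camera adjusted p = 0.765; median -0.09 and mean 0.04). It was the integrin gene Itgb3 (-1.64 ± 0.29), whose call was lost without control replicate 1 or 2 or LPS-O2 replicate 2 or 3 (adjusted p from 0.0559 to 0.0730).

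The chemokine list was called as higher. Of 32 chemokine genes, 9 rose and 1 fell (10 and 1 when adjusted over the list alone; list mean 1.04 ± 0.18; camera adjusted p = 0.000174, adjusted p = 0.105 with an estimated correlation). Besides the chemokines above, Ccl2, the main ligand of Ccr2, rose by 1.72 ± 0.29 to 19.15 ± 0.24 (SD, n = 3), close to the top of the scale, where a difference can be compressed. Of the 10 calls, 5 held without control replicate 2, 6 without control replicate 3 and 5 without LPS-O2 replicate 2, and Ccl2 missed the threshold in each of these fits (adjusted p = 0.0760, 0.0527 and 0.0695). Of 21 chemokine receptor genes, 2 fell and 1 rose, over all genes and over the list alone. They were Cxcr5 (-2.40 ± 0.29), which guides B cells to follicles, Ccr7 and Xcr1, and all 3 calls held whichever array was left out (list not called, camera adjusted p = 0.170; called as lower without shared genes, adjusted p = 0.0115). Of 30 NF-kB inflammatory mediators, 2 rose (2 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.965; median -0.01 and mean 0.21). These were the macrophage growth factor gene Csf1 (3.81 ± 0.56) and oncostatin M (Osm, 2.99 ± 0.46), which missed the threshold without control replicate 2 (adjusted p = 0.0562) or LPS-O2 replicate 2 (0.0519) and with the Y-linked covariate (0.0779).

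Of the classical cytokine genes Il1b, Il6, Il10 and Tnf, none passed over all 6 arrays, and Tnf and Il10 did under some other settings. Il1b was 17.63 ± 0.49 in controls and 17.82 ± 0.88 in LPS-O2 (SD, n = 3; adjusted p = 0.892). Il6 was 1.41 ± 0.55 higher (SE; adjusted p = 0.229), Il10 1.67 ± 0.48 higher (0.103) and Tnf -2.73 ± 0.66 (0.0564). Tnf passed as lower without control replicate 1 (0.0392) or 3 (0.0233), without the dimmest probe sets (0.0492), after quantile normalization (0.0448), with array weights (0.0290) and with Hba-a1 as a covariate (0.00405), and Il10 as higher with the Y-linked covariate (0.0475) and with the replicate block (0.0234). Nos2 (1.71 ± 1.14, adjusted p = 0.522) ranged from 11.6 to 17.0 within LPS-O2, and Arg1 (2.02 ± 0.66, 0.151) from 6.39 to 9.33. Of 24 Toll-like receptor signalling genes, 4 rose (7 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.0737, but called as higher without control replicate 1, 0.0487, or LPS-O2 replicate 3, 0.0137, with the Y-linked covariate, 0.0436, with Hba-a1 as a covariate, 0.0484, and with control replicate 3 as the only control, 0.0358). They included Tlr3, the flagellin receptor gene Tlr5 (1.33 ± 0.30) and the lipopolysaccharide receptor gene Tlr4 (1.26 ± 0.28), while its coreceptor gene Cd14 was 0.96 ± 0.23 higher without passing (adjusted p = 0.0522), but passed without the dimmest probe sets (0.0447), after quantile normalization (0.0415), with array weights (0.0365) and with trend and robust in eBayes (0.0137). Tlr4 held only without LPS-O2 replicate 3 and Tlr5 only without control replicate 1 among the fits with 1 array left out (adjusted p up to 0.137 and 0.162). No Toll-like receptor call held without control replicate 2, 1 held without control replicate 3, LPS-O2 replicate 1 or LPS-O2 replicate 2, and 2 without control replicate 1 or LPS-O2 replicate 3. Of 36 type I interferon genes, 2 fell (3 lower and 2 higher when adjusted over the list alone), Mx1 (-1.44 ± 0.31) and Zbp1 (-1.22 ± 0.22). Both calls were lost without control replicate 3, LPS-O2 replicate 2 or LPS-O2 replicate 3 (adjusted p from 0.0514 to 0.106), and Mx1 also without control replicate 1 (0.0915) or LPS-O2 replicate 1 (0.0777); the list was not called (camera adjusted p = 0.867; median -0.04 and mean 0.03). Of 24 interferon gamma genes, 1 rose, Ciita (1.37 ± 0.30), the activator of class II genes (3 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.729). Of 12 inflammasome genes, 1 fell (3 when adjusted over the list alone), Casp4 (-0.92 ± 0.20), which senses cytosolic lipopolysaccharide. The inflammasome list was called as lower (mean -0.33 ± 0.29; camera adjusted p = 0.0124, adjusted p = 0.244 with an estimated correlation), but not without control replicate 1 (mean -0.202, 0.0557), with the Y-linked covariate (-0.0985, 0.261) or with control replicate 3 as the only control (-0.0856, 0.305). The mean was -0.579 without LPS-O2 replicate 1, -0.216 without LPS-O2 replicate 2 and -0.208 without LPS-O2 replicate 3. Casp4 missed the threshold without any 1 array except LPS-O2 replicate 1 (adjusted p up to 0.137), and Ciita without control replicate 1 or 2 or LPS-O2 replicate 2 or 3 (up to 0.144). Of 24 complement genes, 2 fell and 1 rose (5 and 7 when adjusted over the list alone; camera adjusted p = 0.761). Of these 3 calls, 1 held without control replicate 2 and 1 without LPS-O2 replicate 2. The central component C3 fell by 3.12 ± 0.43, and of the complement receptor 3 chains Itgb2 fell while Itgam rose by 2.19 ± 0.36, a call lost without control replicate 2 (0.0584) or LPS-O2 replicate 2 (0.0614) and with the Y-linked covariate (0.0629).

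Genes of matrix remodelling were higher in LPS-O2. Of 32 measured, 9 rose and none fell, 17 rose when adjusted over the list alone, and 30 had a positive difference (list mean 1.5 ± 0.21; camera adjusted p = 9.52e-11, adjusted p = 0.149 with an estimated correlation). Spp1, Timp1, Mmp14 and Mmp12 led the list. Also called, and named after their values were seen, were the macrophage receptor gene Trem2 (3.35 ± 0.57), Gpnmb (2.66 ± 0.46), the protease genes Ctsl (1.94 ± 0.44) and Ctsb (0.88 ± 0.20), and Timp2 (1.15 ± 0.26). Of the 9, 4 stayed past the threshold without control replicate 2 or LPS-O2 replicate 2, 5 without control replicate 3 or LPS-O2 replicate 3, and 7 with the Y-linked covariate. Of 26 genes of alternative macrophage activation, 6 rose and 2 fell (11 and 3 when adjusted over the list alone; list mean 1.04 ± 0.30; camera adjusted p = 0.000137, adjusted p = 0.303 with an estimated correlation; mean 1.59 with control replicate 3 as the only control). The scavenger receptor gene Msr1 rose by 2.91 ± 0.47 with Ccl17 and Ccl22, while Alox15 and Klf4 (-1.78 ± 0.33) fell. Of these 8, 5 held without control replicate 2 and 5 without LPS-O2 replicate 2. Klf4 was lost without control replicate 1 (adjusted p = 0.0670) or 2 (0.0950) and with the Y-linked covariate (0.147), and Msr1 without control replicate 2 (0.0550) or LPS-O2 replicate 2 (0.0502). Of 24 angiogenic factor genes, 1 rose and 1 fell (5 and 2 when adjusted over the list alone; camera adjusted p = 0.0884, and 0.0241 without LPS-O2 replicate 2). Neuropilin 2 (Nrp2) rose by 3.82 ± 0.27 and angiopoietin 1 (Angpt1) fell by 2.20 ± 0.28, each whichever array was left out. Vegfa was 2.16 ± 0.59 higher without passing (adjusted p = 0.0877), and passed without LPS-O2 replicate 3 (0.00851) and with array weights (0.0455).

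Lysosomal, lipid and antigen presentation genes included further changes. Of 37 phagocytosis and lysosome genes, 5 rose and 1 fell (12 and 1 when adjusted over the list alone; list mean 0.62 ± 0.21; camera adjusted p = 5.12e-06, adjusted p = 0.335 with an estimated correlation; mean 0.978 with the Y-linked covariate and 0.987 with control replicate 3 as the only control), led by Fcgr2b and Msr1 upward with Fcgr3a downward. Fc receptor genes are similar in sequence, and signal may be shared among them. Of these 6 calls, 1 held without control replicate 2, 2 without control replicate 1 or LPS-O2 replicate 2, and 3 without control replicate 3 or LPS-O2 replicate 3. Of 30 lipid uptake and storage genes, 4 rose and 1 fell (4 and 3 when adjusted over the list alone), led by Fabp5 and Apoe upward and Cidec downward. The lipid list was not called (camera adjusted p = 0.867), but was called as higher with the Y-linked covariate (adjusted p = 0.00212) and with control replicate 3 as the only control (0.00617). Of its 5 calls, 2 held without control replicate 2, 1 without LPS-O2 replicate 2 and 3 without LPS-O2 replicate 3. Apoe missed the threshold in each of these fits (adjusted p = 0.0584, 0.0940 and 0.0756). No cholesterol synthesis gene of 21 passed, over all genes or the list alone (camera adjusted p = 0.867), with Insig1 at -0.76 ± 0.22 (adjusted p = 0.105) and Cyp51 at -0.81 ± 0.27 (0.159). Of 18 class II presentation genes, 6 rose and none fell (11 higher and 1 lower when adjusted over the list alone; list mean 0.77 ± 0.09; camera adjusted p = 7.87e-07, adjusted p = 0.105 with an estimated correlation), led by the lysosomal protease gene Lgmn (2.01 ± 0.24) and Ciita. Of these 6, 1 held without control replicate 2 and 1 with the Y-linked covariate, 2 without LPS-O2 replicate 2 or 3, and 3 without control replicate 1.

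Genes of leukocyte adhesion and migration were lower. Of 26, 11 fell and 3 rose (12 and 4 when adjusted over the list alone; list mean -0.75 ± 0.08; camera adjusted p = 1.16e-05, adjusted p = 0.105 with an estimated correlation). S1pr5 and Pecam1 fell most, and Itgam and the laminin receptor chain Itga6 (1.29 ± 0.20) rose most. Of these 14 calls, 6 held without control replicate 2 or LPS-O2 replicate 2, 9 without LPS-O2 replicate 3 and 8 with the Y-linked covariate. Itga6 missed the threshold without control replicate 2 (adjusted p = 0.0569) or LPS-O2 replicate 2 (0.0537). Of 37 immediate early and dissociation response genes, which enzymatic or mechanical release of cells can induce, 3 rose and 6 fell (5 and 8 when adjusted over the list alone; camera adjusted p = 0.494; median 0.08 and mean -0.13). Ier3 rose by 2.30 ± 0.30 and the nuclear receptor gene Nr4a2 by 1.43 ± 0.28, while Klf2, a factor of quiescent lymphocytes, fell by 3.20 ± 0.29 with Hspa1a. Of these 9 calls, 3 held without control replicate 2 and 5 without LPS-O2 replicate 2. Nr4a2 was lost without control replicate 2 or 3 or LPS-O2 replicate 1 or 2 (adjusted p from 0.0513 to 0.108).

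The cell cycle lists, DNA replication and mitosis, were called as higher by camera at the preset correlation. The fry test called neither (adjusted p = 0.0564 for DNA replication and 0.0694 for mitosis). All 32 DNA replication genes had a positive difference, 5 of them passed, and 16 did when adjusted over the list alone (list mean 0.75 ± 0.19; camera adjusted p = 9.52e-11, adjusted p = 0.263 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose by 1.75 ± 0.23 and thymidylate synthase (Tyms) by 1.88 ± 0.36. Rrm2 held whichever array was left out, and Tyms only without LPS-O2 replicate 1 (adjusted p up to 0.106 otherwise). Of the 5 calls, 1 held without control replicate 2, 2 without control replicate 3, LPS-O2 replicate 2 or LPS-O2 replicate 3, and 3 without control replicate 1. Of 29 mitosis genes, 4 rose and none fell (14 higher when adjusted over the list alone; list mean 0.69 ± 0.20; camera adjusted p = 6.54e-08, adjusted p = 0.292 with an estimated correlation), led by cyclin A2 (Ccna2, 1.44 ± 0.23) and Pbk (1.42 ± 0.26). None of these 4 held without control replicate 2, LPS-O2 replicate 2 or LPS-O2 replicate 3, 1 held without control replicate 3 and 2 without control replicate 1. The proliferation marker Mki67 was 9.28 ± 0.83 in controls and 9.10 ± 0.35 in LPS-O2 (SD, n = 3; adjusted p = 0.887). With the Y-linked covariate 1 of the 5 replication calls and none of the 4 mitosis calls held. Of 24 p53 target genes, 3 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.184). The cell cycle inhibitor gene Cdkn1a rose by 2.98 ± 0.35 and held whichever array was left out. The kinase gene Plk2 rose by 2.49 ± 0.42, a call lost without control replicate 2 (adjusted p = 0.0547) or 3 (0.0507), and the apoptosis gene Apaf1 fell by 1.04 ± 0.22, a call lost in each of the 6 such fits (0.0588 to 0.129). Of the 4 calls, 1 held without control replicate 2 or 3 and 2 without LPS-O2 replicate 2 or 3.

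Of 5 lists tied to oxygen, energy metabolism and cell stress, 3 were called as higher, and none was with an estimated correlation. Of 36 NRF2 and antioxidant genes, 3 rose and none fell (10 higher and 1 lower when adjusted over the list alone; list mean 0.53 ± 0.13; camera adjusted p = 0.000115, adjusted p = 0.303 with an estimated correlation), led by sulfiredoxin (Srxn1, 2.08 ± 0.36) and Gstp1 (1.42 ± 0.30). None of the 3 held without control replicate 2 or 3 or LPS-O2 replicate 2, and 1 held without LPS-O2 replicate 3. Haem oxygenase (Hmox1) was 1.96 ± 0.49 higher (adjusted p = 0.0669; 0.0277 with the Y-linked covariate), Nqo1 0.89 ± 0.33 higher (0.198), and the mitochondrial dismutase Sod2 14.56 ± 0.10 and 14.48 ± 0.92 (SD; 0.954). Of 46 oxidative phosphorylation genes 43 had a positive difference, with 1 past the threshold, Uqcrb (1.13 ± 0.21), and 5 when adjusted over the list alone (list mean 0.49 ± 0.11; camera adjusted p = 2.96e-10, adjusted p = 0.299 with an estimated correlation). Uqcrb missed the threshold without any of the 3 controls or LPS-O2 replicate 3 (adjusted p from 0.0593 to 0.0798). Of 23 glycolysis genes, 2 rose, over all genes and over the list alone, the hexokinase genes Hk3 (2.10 ± 0.37) and Hk2 (1.74 ± 0.28). The list mean rose by 0.44 ± 0.19 (camera adjusted p = 0.00607; adjusted p = 0.379 with an estimated correlation), a call lost without LPS-O2 replicate 1 (mean 0.261, 0.169) or without shared genes (mean 0.299, 0.104). Neither hexokinase held without control replicate 2 (adjusted p = 0.0760 for Hk3 and 0.0603 for Hk2), and Hk3 did not without LPS-O2 replicate 2 (0.0704) or 3 (0.0789). Of 25 HIF target genes, 1 rose, Hk2, and 3 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.867), including Ak4 (-2.45 ± 0.34) and Bnip3l (-1.14 ± 0.23), which held only without LPS-O2 replicate 2 (adjusted p up to 0.114 otherwise). Of the 4 HIF calls, 1 held without control replicate 2, 2 without control replicate 1 or LPS-O2 replicate 3, and none with the Y-linked covariate. Of 29 unfolded protein and integrated stress response genes, 1 rose, asparagine synthetase (Asns, 2.09 ± 0.35; adjusted p = 0.0628 without control replicate 2), with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.373; called as higher with the Y-linked covariate, 0.0436).

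Of the 43 lists, camera with a preset correlation of 0.01 called 21, of which 13 were higher and 8 lower. None was called with an estimated correlation, where the smallest adjusted p was 0.105. The fry test, which asks whether the genes of a list move on balance one way, called 9 lists. These were the lists of T cells, B cells, mast cells, dendritic cells, matrix remodelling, class II presentation, chemokines, oxidative phosphorylation and adhesion. The fry test of change in either direction called 39. Lists share genes, so their calls are not independent of each other.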

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

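All 880 calls kept their direction in each refit that tested them. As the values of the groups did not overlap in any of the 880, most refits could not have reversed a direction. Only those with a covariate or another normalization could. No named gene or list called in the main fit was called in the opposite direction in a refit. Differences that were not called could change sign. The mean of the alveolar macrophage list went from -0.358 to 0.341 with the Y-linked covariate and to 0.297 with control replicate 3 as the only control. Filtering, normalization and the variance model gave 874 (median centring) to 1144 (array weights) calls, at least 2-fold as a further condition 790, and 1 probe set per named gene, adjusted over these alone, 681 (640 genes when adjusted over the whole table). The fits with covariates and with control replicate 3 alone were chosen after seeing the data. Leaving out 1 array gave 275 to 899 calls, 107 to 472 higher and 168 to 427 lower. Fewer arrays lower the power of the test, and the rise without LPS-O2 replicate 1, which stands apart in neutrophil genes, goes the other way (the cause was not tested). Of the 880 calls, 270 held without control replicate 2, 305 without LPS-O2 replicate 2 and 659 without LPS-O2 replicate 1. At an adjusted p under 0.1, 1468 were called, 700 higher and 768 lower, by construction more. At an unadjusted p under 0.05 with at least 2-fold, 1284 were called, 632 higher. The 120 named genes measured include some that were not called in the main fit and had no call to lose. Of the 120, 12 to 42 lost their call when 1 array was left out, and 34 lost and 3 gained it with the Y-linked covariate. Those that lost it, at an adjusted p from 0.0505 (Itga6) to 0.255 (Slc39a2), were Ak4, Apaf1, Bnip3l, Casp4, Ccna2, Cdh1, Cidec, Ciita, Enpp3, Fcgr3a, Foxp3, Gata3, Gpd1, Gstp1, Hk2, Hspa1a, Itga6, Itgam, Itgb2, Itgb3, Klf4, Mx1, Osm, Pbk, Pdpn, Pla2g2d, Sirpb3, Slc39a2, Srxn1, Tlr3, Tlr4, Tnfrsf18, Tyms and Uqcrb. Of these, the log2 difference of Fcgr3a (-2.06), Gpd1 (-1.84) and Sirpb3 (-2.28) shrank by over 1.5 times. With trend and robust in eBayes, 9 lost it, Pld3 (0.0761), Pla2g2d (0.0620), Prf1 (0.0636), Fcgr3a (0.0900), Sirpb3 (0.118), Gpd1 (0.119), Apoe (0.126), Slc39a2 (0.155) and Hspa1a (0.183), and Ptprc (0.0182) and Cd14 (0.0137) gained it.

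With the Y-linked covariate 501 were called (255 higher, 246 lower), with control replicate 3 alone against LPS-O2 182 (94 higher, 88 lower), and with Hba-a1 as a covariate 685 (259 higher, 426 lower). The first uses 1 more term and the next 2 fewer arrays, which lowers power, and how much of the loss comes from the sex of the pups was not tested. The number of called lists was 19 to 25 over the refits, the settings without shared genes and with the mean of probe sets included. It was 0 with an estimated correlation and 9 with fry. The preset correlation assumes nearly independent genes, and markers of a cell type are not independent.

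With the replicate number as a block, 576 probe sets were called, 253 higher and 323 lower, and 529 of these were among the 880. No source says that equal numbers mark a pair (the replicate block). The deviations of same-numbered arrays from their group means correlated at -0.0199, 0.00558 and -0.0635, while arrays of other numbers reached 0.0816. With the block the monocyte list was no longer called (adjusted p = 0.0570) and the neutrophil list was (0.0286), and no other list call changed.

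With no detection calls, which probe sets lie above background cannot be said. On simulated data 8% of 2-fold changes were called with 200 probe sets changed and 57.4% with 10% changed, so a gene that did not pass can still differ by 2-fold. The pseudocount alternative was not run, since the values are on a log scale.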

Other observations

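The gene families in this paragraph were looked up after the values were seen. All 7 measured genes of the Gimap family, small GTPases found mostly in lymphocytes, fell, with a median of -2.12 and a range from -3.28 (Gimap9) to -1.63 (Gimap1), also after quantile normalization (median -2.13) and median centring (-2.11). Gimap4 fell by 3.16 ± 0.29 (SE) and Gimap7 (-2.79 ± 0.24) did as well. Of 24 genes of the vacuolar proton pump and its accessory proteins, which acidify lysosomes, 3 rose and 22 had a positive difference under each of these scalings (median 0.26), with Atp6v0a1 higher by 2.64 ± 0.33. Of 71 cytosolic ribosomal protein genes and close relatives, 64 had a negative difference (65 after quantile normalization), with a median of -0.33, while 1 rose and 1 fell. None of 13 S100a genes was called by limma.

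Single genes outside the fixed lists, also picked after their values were seen, were among the called. The iron exporter gene Slc40a1 rose by 3.26 ± 0.60 (adjusted p = 0.0209), the haem transporter gene Slc48a1 by 2.28 ± 0.26 (0.00271) and the ferrireductase gene Steap3 by 2.20 ± 0.21 (0.00149). The Notch pathway transcription factor gene Rbpj rose by 2.68 ± 0.19 (0.000501), while the Notch target Hes1 is among the falls. The aryl hydrocarbon receptor gene Ahr rose by 2.29 ± 0.28 (0.00327), and tissue factor (F3), which starts coagulation, by 3.12 ± 0.69 (0.0402). The chromatin organiser gene Satb1 (-2.99 ± 0.30, 0.00177) and Cd69 (-2.42 ± 0.23, 0.00149), an early activation marker, fell.

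Of the tests in the next 4 paragraphs, those of the difference between lists were chosen only after the result was seen, and the covariates were added after the Y-linked and haemoglobin values were known. Among the 10 splits of the 6 arrays into 3 and 3, 1 gave 880 calls, the real one, and the highest number in another split was 0, with 519 to 1179 probe sets at an unadjusted p under 0.05. For lists, 1 of the 10 splits, again the real one, gave 21 calls, and the others gave 5 to 19. Camera at the preset correlation thus called lists in splits with 0 probe sets called, so the number of called lists says little about the groups. In each case 10 splits are too few for a share under 0.05. Every other split also puts arrays of both groups on each side, so the group difference widens the spread there and lowers the number of probe sets called.

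The T cell list was lower by 2.08 in LPS-O2. With the Y-linked mean as a covariate the shift was -2.48 (95% interval -2.77 to -2.18), and with Hba-a1 it was -1.92 (-2.54 to -1.30), both beyond 50% of the unadjusted shift. The first argues against the sex of the pups as the whole source, though it leans on control replicate 3, the only control with high Y-linked values. Hba-a1 comes from red cells, which the CD45 gate should remove. It cannot show how many blood lymphocytes were sorted, so blood in the control samples stays open. A lower lymphocyte share alone would raise other cell types alike, and the shifts of the interstitial and alveolar macrophage lists differed by 1.99 (0.856 to 3.12). The interval was -0.0319 to 4.03 with the Y-linked covariate, and the alveolar genes went both ways (median 0.0933, SD over genes 1.49), so this difference does not decide. Of 20 monocyte genes, 7 fell and none rose (8 lower and 4 higher when adjusted over the list alone). Of 20 interstitial macrophage genes, 5 rose and none fell. These genes did not rise alike, but the monocyte list mean was only -0.33 ± 0.28 (SE). Whether lymphocytes also express some of the monocyte genes was not tested. The counts therefore do not decide on a lower lymphocyte share as the only change. Of the monocyte genes, 11 are also in other lists. A lower share of T cells or lower expression per T cell may each underlie the pattern, and bulk values cannot separate them.

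The matrix remodelling list was higher, led by Spp1, Timp1, Mmp14 and Mmp12. With the Y-linked covariate the shift was 1.82 (1.19 to 2.45). It exceeded the shift of the mesenchymal list by 1.57 (0.621 to 2.51), which argues against mesenchymal cells that passed the gate as the source of the list's mean shift. The comparison does not cover single matrix genes, nor epithelial or endothelial cells that passed the gate. It also exceeded that of the alveolar macrophage list by 1.86 (1.11 to 2.61), but since the genes of that list go both ways with a spread (SD 1.49) about as large as the shift, a higher share of all macrophages stays open. Another hypothesis is that a macrophage population marked by Spp1, Trem2, Gpnmb and Fabp5 may be larger or more active after the exposures. It was not tested here, since bulk values do not tie the genes to 1 cell type (11 of the 32 are also in other lists), and expression in single cells would test it.

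The mast cell list was higher. With the Y-linked covariate the shift was 1.03, with a 95% interval of 0.0401 to 2.02 that includes values under 50% of the unadjusted 1.13, so a part played by the sex of the pups stays open. The 1.99 between the macrophage lists does not decide on a lower lymphocyte share and nothing else here either. Of the mast cell genes 8 rose and none fell, while of the monocyte genes 7 fell and none rose (8 lower and 4 higher when adjusted over the list alone). For the reasons given for the T cell list, these counts do not decide on it either. The shift exceeded the mean of those of the neutrophil, alveolar macrophage and monocyte lists by 1.18, with an interval of -0.317 to 2.68 that includes 0, so a lower lymphocyte share beside changes in other cells stays open. More mast cells or more transcript per cell may also underlie it, which no test here addressed.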
